A study of Mus musculus with 3 samples.

How the data were processed

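Small RNAs bound to Tdrd1 or to Mili were sequenced from mouse testis of the C57BL/6 strain in 3 libraries, 1 per group. Tdrd1 is a Tudor-domain protein of germ cells, and Mili (gene symbol Piwil2) is a Piwi protein that carries piRNAs, the small RNAs of animal germ cells. Per the labels, 1 library came from a Tdrd1 immunoprecipitate of adult testis, 1 from a Mili immunoprecipitate of adult wild-type testis and 1 from a Mili immunoprecipitate of testis lacking Tdrd1 at 15 days after birth. Per the labels' protocols, RNA of about 28 to 30 nt was eluted from a gel beside a radioactive spike and made into libraries with an Illumina small RNA kit. Per the file headers, positions refer to NCBI mouse build 37, and the submitters' processing notes name mm9, the same build. The aligner, the number of mismatches allowed and the treatment of sequences with several genome positions are not given in the sources used here.

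The table used here was deposited by the authors as a single list for the series, in which each of 2219118 distinct sequences stands once with its chromosome, start and end. The 3 columns hold no read number, no strand and no library, so that the deposited unit is a listed sequence, neither a count nor a normalised level. Every listed interval had the length of its sequence, and all letters were A, C, G or T. The sequencing depth of each library is therefore unknown. The comparisons written down before the data were examined (Mili from knockout against Mili from wild type, and Tdrd1 against Mili from wild type) need a library for each read and were not computed. The pooled list was described in their place, with the same measures of length, first base and the base at position 10, annotation, opposite-strand overlap and genomic windows, each distinct sequence weighing 1.

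Strand was inferred from the list. A sequence and an overlapping neighbour on the same strand must carry the same bases at the same positions, and neighbours on opposite strands must carry complementary bases. Strand was called where stretches of 12 nt shared between overlapping sequences fixed the orientation, which gave a strand to 1757424 sequences (79.2%), 50.3% of them on the plus strand. Among positions covered by several sequences, 0% of bases differed from the most common base. The sequences are thus exact copies of 1 sequence at each place.

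Genes were assigned by sequence and not by coordinate, since the annotation used (GENCODE vM21) describes another build, GRCm38. Each sequence was searched over its whole length and on both strands in the 55450 annotated genes' transcripts, by an exact seed of 18 nt and then base by base, and a match was kept where the transcript lies on the listed chromosome. A match was found for 58.8% of sequences. In 99.9% of the matches that could be compared, the inferred strand was the one implied by the match. That is the gene's strand for a sense match and the opposite strand for an antisense match. Of the matched sequences, 0.527% also matched transcripts of another chromosome. A sequence matching several classes was split equally between them. Sequences that match no annotated exon cover introns, unannotated transcripts and repeats together, because no genome or repeat annotation was used here. The list of transposon families fixed beforehand was not analysed here for that reason. U1, U2 and nuclear tRNA were not searched by name, although small nuclear RNA genes were counted as a class. 18S rRNA was not searched under its own name, since 0 entries of the annotation carried it, and 28S rRNA was not searched.

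Coordinates in the text are those of the deposited list, 1-based on mm9, and a range given for a gene runs from the first start to the last end of the sequences matching it. Gene levels are distinct sense sequences per kb of merged exon. Untranslated and coding parts were taken from the annotated coding sequence of each matched transcript, by the midpoint of the sequence, and the expected share of each part is its share of the length of the same transcripts. Windows of 20 kb were counted by sequence start. The overlap of 5′ ends on opposite strands was counted for sequences of 24 to 32 nt that had a neighbour on the same strand. The number of pairs at 10 nt was set against overlaps of 1 to 9 and 11 to 20 nt, as a ratio to their mean and as a distance in SDs of those 19 values, given below as z. Each list of genes was compared with 10000 random lists of protein-coding genes matched on exon length in 20 bins, and the percentile of its median is a description of these libraries.

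Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Neighbouring sequences of 1 transcript are not independent, so real errors are larger. There are no replicates and no test across conditions. Genes were named by the rule written before the data were examined, adapted to the pooled list: the 10 with most sense sequences among protein-coding and among noncoding genes, the 10 with most antisense sequences, the 10 richest windows and 7 fixed gene lists. Ratios between libraries, the other part of that rule, were not computed, and some genes that the rule takes are not reported here.

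The procedures were tested on simulated data. In a random genome holding 400 precursors the strand call was right for 100% of called sequences, at 95625 sequences without planted pairs and at 103547 with 10 planted pairs per precursor. The ratio at 10 nt was 1.02 (z 1.41) without planted pairs and 1.89 (z 61.2) with them. The transcript search found 100% of 2000 planted sense pieces and 100% of 2000 antisense pieces, and matched 0% of 2000 random sequences. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Alternatives tried were counting each 5′ end once, restricting lengths to 24 to 32 nt, leaving out structural RNA and microRNA genes, counting a sequence in every class it matches, other window sizes and numbers, and subsets of sequences for the overlap.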

Results

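The series asks which small RNAs accompany Tdrd1 and Mili in the testis, and whether those bound to Mili change when Tdrd1 is missing. It holds 3 libraries of small RNAs from immunoprecipitates, 1 each for Tdrd1 from adult testis, Mili from adult wild-type testis and Mili from Tdrd1-knockout testis at 15 days after birth. The knockout animals thus differed from the wild type in the age given as well as in genotype. The deposited list pools the series: it names 2219118 distinct sequences with 1 position each, and it carries no library column. Mili from knockout could therefore not be set against Mili from wild type, nor Tdrd1 against Mili, and the targeted gene could not be checked in each library. In the pooled list the Tdrd1 transcript matched 133 sense and 6 antisense sequences. All values below describe the pooled small RNAs of the 3 immunoprecipitates, counted as distinct sequences. Read numbers were not used, so an abundant and a rare small RNA weigh the same.

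The pooled small RNAs had the size and first base of piRNAs, but the gel set the sizes, so that length alone does not identify them. Sequences ran from 18 to 36 nt with the most common length at 27 nt (570505 sequences, 25.7% of the list), followed by 26 nt (21.1%) and 28 nt (19.5%). Lengths of 24 to 32 nt made up 98.1%. Within them the range of 24 to 28 nt, where Mili-bound piRNAs are known to lie, held 78.2% of the list and 29 to 32 nt held 19.9%. The most common length lay just below the 28 to 30 nt that the protocol names for the gel. U was the first base of 68.7% of sequences of 24 to 32 nt (95% interval 68.7 to 68.8%), against 14.4% for A, 8.84% for C and 7.99% for G, whereas U made up 17.1% at position 2. The share starting with U rose with length, from 60.7% at 24 nt through 67.7% at 27 nt to 80.5% at 32 nt. When each 5′ end was counted once the share was 60.8%, and among 5′ ends with 5 or more 3′ ends it was 85.8%.

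**Figure D1:**
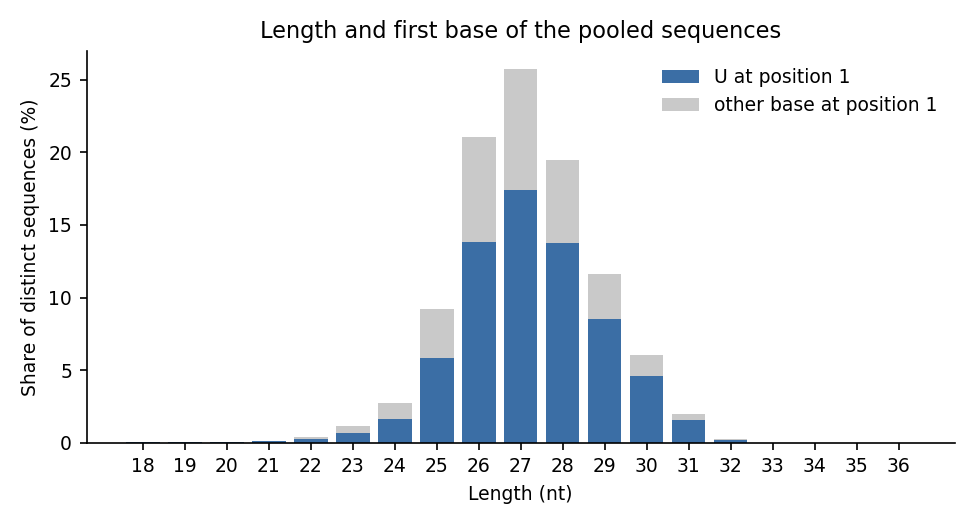
Share of the 2219118 pooled distinct sequences at each length in nt, in percent, with sequences starting with U in blue and those starting with another base in grey. The most common length is 27 nt, and U starts most sequences at each length from 24 to 32 nt.

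A at position 10, the mark of secondary piRNAs made in the amplification cycle (the ping-pong cycle, in which a piRNA bound to a Piwi protein guides the cut that makes the 5′ end of the next one), did not stand out. It was found in 32.6% of sequences of 24 to 32 nt (32.5 to 32.6%), next to 31.6% A at position 9 and 32.3% at position 11. Among sequences that did not start with U the share was 33.1% (33.0 to 33.2%). The highest A share was at position 5, with 41.9%.

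Exons of protein-coding genes were the largest source that could be named. Sequences matching them in the sense direction made up 51.5% of the list (51.4 to 51.6%). Another 41.2% (41.1 to 41.3%) matched no annotated exon, 3.82% matched long noncoding RNAs, 2.73% matched the antisense strand of an exon, and 0.615% matched pseudogenes. Structural RNAs (ribosomal, small nuclear, small nucleolar and other short RNAs) made up 0.0867% in the sense direction and microRNA genes 0.0465%. Without the split of shared sequences the sense share of structural RNAs was 0.106%. With every sequence on either strand of a structural RNA gene, also without the split, it was 0.180%, a count chosen after seeing the data. Most of the sequences that the antisense strand added were the 1527 antisense to CT010467.1, annotated as rRNA on the minus strand. They run in the direction of Gm42418, a noncoding gene annotated on the plus strand in the same window, so they need not be antisense to rRNA. Sense matches to genes were 16 times as frequent as antisense matches. Sequences from protein-coding exons started with U in 67.7%, those without an exon match in 70.4% and those sense to structural RNAs in 42.0% (35.8% with both strands). Of the structural RNAs fixed beforehand, 5S rRNA genes matched 168 sequences, the let-7 microRNA genes 52 and the miR-34 genes 14. A further 754 sequences matched small nuclear RNA genes.

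Protein-coding genes contributed unequally. Of 21951 annotated genes, 15575 had at least 1 sense sequence and 1328 had 200 or more, and the 10% of genes with most sequences held 60.3% of gene matches. The tyrosine kinase gene Abl2 had 2397 sense sequences (222 per kb of exon, chromosome 1 from 158489135 to 158579642). Pou2f1, the gene of the transcription factor Oct-1, had 2330 (140 per kb), and Trim71, a regulator of stem cell mRNAs, had 2065 (221 per kb, chromosome 9 from 114416409 to 114473474). Smcr8 followed with 1891, the heterochromatin protein gene Cbx5 with 1798, the translation inhibitor gene Eif4ebp2 with 1738 (300 per kb, the highest density of the genes named here) and Zbtb37 with 1686. D10Wsu102e had the highest number, 4464, but its merged exons span 123179 bp, so that its density of 36.2 per kb was the lowest of them. Between 0 and 11 antisense sequences matched each of these genes. U started from 64.3% (Eif4ebp2) to 78.2% (Zbtb37) of their sequences of 24 to 32 nt.

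Within mRNAs the sequences lay more often in 3′ untranslated regions than length alone gives. Of 1135039 sequences matching coding transcripts, 51.4% (51.3 to 51.5%) lay in the 3′ untranslated region, where 45.6% was expected from the length of the same transcripts. The coding sequence held 44.5% (44.4 to 44.6%) against 47.5% expected, and the 5′ untranslated region 4.05% (4.02 to 4.09%) against 6.91%. U started 75% of sequences in 3′ untranslated regions, 59.4% in coding sequence and 62.3% in 5′ untranslated regions.

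The lists of germ cell genes had higher medians than the lists of genes of the somatic cells of the testis, with members that overlap in range. The lists were each set against random lists, and the difference between them was not tested. The median over the 8 spermatogonial genes was 61.8 sense sequences per kb, at percentile 99.99 of random lists, whose own median was 3.12. All 8 had sequences, among them Stra8, the gene induced by retinoic acid at entry to meiosis (88.7 per kb), the RNA-binding protein gene Dazl (81.4) and the receptor gene Kit (15.8). The 8 meiotic genes had a median of 48.5 per kb, above all 10000 random lists. Sycp3 and Sycp1, genes of the synaptonemal complex, stood at 165 and 75.1 per kb and the sperm lactate dehydrogenase gene Ldhc at 87.3, whereas Spo11, which makes the meiotic double-strand breaks, stood at 3.57. The 10 haploid spermatid genes had a lower median of 12.2 per kb, at percentile 99.17 because random lists of such short genes had a median of 0.160. The transition protein gene Tnp1 stood at 82.4 per kb and the protamine gene Prm2 at 41.4, while Acr and Spata18 stood at 3.83 and 3.32. The 12 genes of the piRNA pathway had a median of 20.6 per kb (percentile 99.74), and each had at least 26 sequences. Among them Mael had 87.1 per kb, Mov10l1 81.5, Piwil2 (the gene of Mili itself) 62.4, Tdrd1 24.4 and Piwil4 4.83.

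The 8 genes listed for Sertoli cells, the somatic nurse cells of the tubules, had a median of 2.44 per kb, at percentile 47.78. Ctsl, a cathepsin gene, stood at 15.1 per kb and Cst12 at 12.2, Sox9 at 1.93 and Wt1 at 0.323, and 0 sequences matched Rhox5. The 6 genes listed for Leydig cells, which make testosterone, had a median of 0.374 per kb at percentile 22.66. Cyp17a1 and Hsd3b6 had 0 sense sequences and Cyp11a1 had 1, but Insl3 stood at 11.2 per kb, and Star, which brings cholesterol into mitochondria, at 19.0 with 78 sense and 51 antisense sequences. The 6 housekeeping genes had a median of 29.7 per kb at percentile 99.74, led by Hsp90ab1 with 90.4, so that a high percentile was not limited to genes of germ cells. Gapdh, which has many processed copies in the mouse genome, had 3 sense sequences. How sequences shared with such copies were placed is not given in the sources used here.

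**Figure D2:**
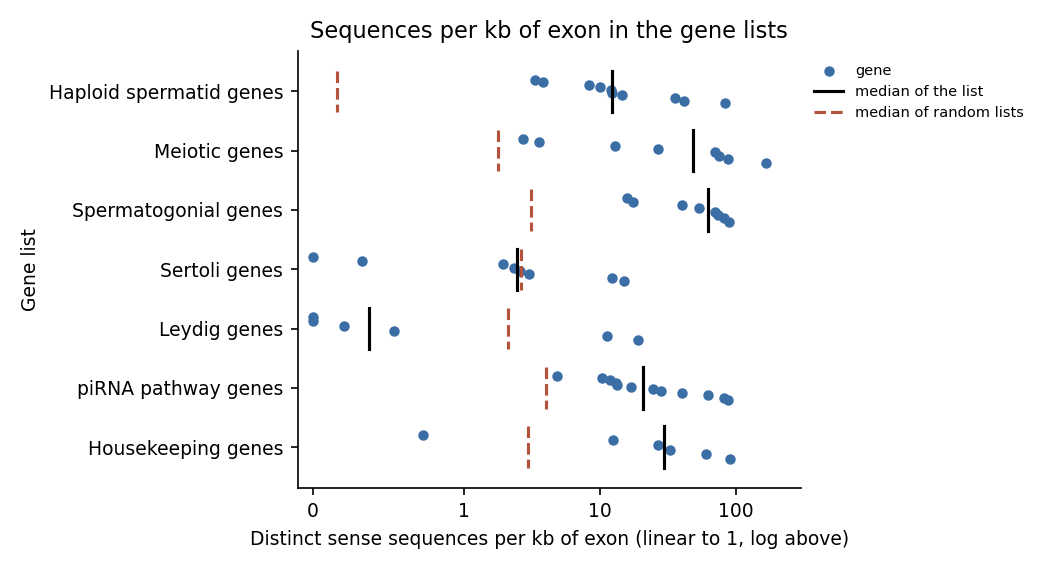
Distinct sense sequences per kb of exon for each gene of the 7 fixed lists (points, axis linear to 1 and logarithmic above), with the median of the list (black line) and the median of 10000 random lists matched on exon length (dashed red line). The spermatogonial and meiotic lists have medians of 61.8 and 48.5 per kb, the Sertoli and Leydig lists 2.44 and 0.374.

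A large part of the list came from few places in the genome. The 100 richest windows of 20 kb, 0.161% of the 62069 windows with a sequence, held 450556 sequences, 20.3% of the list (20.3 to 20.4%). The richest, at 27460001 to 27480000 of chromosome 17, held 15115 sequences. Its neighbours on both sides were the next richest, 27440001 to 27460000 with 13422 and 27480001 to 27500000 with 12442. The strand turned within this region: 0.821% of sequences with a strand lay on the plus strand in the left window, 90.2% (89.7 to 90.7%) in the middle one and 99.5% in the right one. Such pairs of oppositely directed clusters are a known form of piRNA locus in meiotic cells. The next windows were at 67560001 to 67580000 of chromosome 9 (12305 sequences, 0.440% plus), 92400001 to 92420000 of chromosome 2 (10364, 99.8% plus), 24900001 to 24920000 of chromosome 14 (10198, 99.4% plus) and 127740001 to 127760000 of chromosome 6 (10021, 72.5% plus). The last 3 of the 10 were at 80940001 to 80960000 of chromosome 7 (9792, 0.195% plus), 74460001 to 74480000 of chromosome 15 (9562, 92.5% plus) and 67200001 to 67220000 of chromosome 18 (9449, 0.0638% plus).

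**Figure D3:**
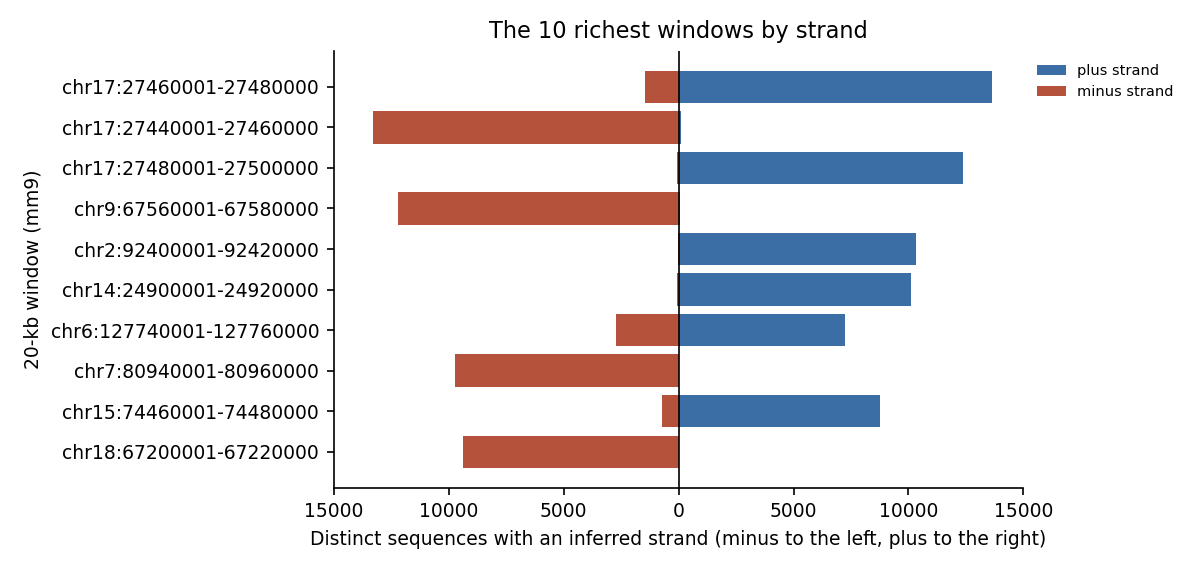
Number of distinct sequences with an inferred strand in the 10 windows of 20 kb with most sequences (mm9), with the plus strand to the right in blue and the minus strand to the left in red. Most windows lie almost wholly on 1 strand, and the strand turns between the neighbouring windows of chromosome 17.

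Across the 100 windows 86 had more than 95% of their sequences on 1 strand and 6 had less than 75%. The most even were at 59100001 to 59120000 of chromosome 15 (48.1% plus) and 77040001 to 77060000 of chromosome 7 (52.2% plus). A median of 4.76% of a window's sequences matched an annotated exon. Among annotated noncoding genes, Gm49794 on chromosome 17 (7571 sense sequences, 27491411 to 27504361) and Gm21269 on chromosome 7 (5705, 80961450 to 80983758) had the most, followed by 1700001L05Rik on chromosome 15 with 3533, Gm10505 on chromosome 17 with 3325 (652 per kb), and Gm10619 on chromosome 7 with 2315, which runs in the opposite direction to Gm21269. AC140207.2, Gm30132, 1700029M20Rik, Gm5878 and Gm21388 had between 1661 and 2272. Inside the windows U started 60.2% of sequences (60.0 to 60.3%), less than the 70.8% (70.7 to 70.8%) outside and the 77.2% of sequences outside that matched no exon. Sequences inside were also shorter, with a mean of 26.4 nt against 27.3 nt outside, and 11.1% of them measured 29 to 32 nt against 22.1% outside.

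Opposite-strand pairs showed the 10-nt offset of the amplification cycle, but few of the sequences counted had a listed partner. Pairs were found by the listed position of each sequence. Partners listed at another copy of a repeat, left out of the list or without a strand call could not be seen. The share that takes part in the cycle is therefore not known. Of the sequences counted, 0.221% at 25 nt and 0.140% at 29 nt had a partner at 10 nt. The list pools 3 libraries, so the members of a pair need not come from the same one. At an overlap of 10 nt between 5′ ends there were 2722 pairs of sequences, 2.35 times the mean of 1160 ± 159 (SD) at the other overlaps and more than the 1395 at the next highest (z 9.85). With each 5′ end counted once there were 681 pairs against 417 ± 51.7 (ratio 1.63, z 5.11). In the 100 richest windows there were 2053 pairs (ratio 2.84, z 12.8). Pairs with both members sense to protein-coding exons numbered 92 (ratio 1.80, z 2.39). An overlap other than 10 nt had 93 such pairs, so 10 nt did not stand out among them. A sense sequence of an mRNA paired with a sequence only antisense to it is left out of that set. The set therefore cannot show whether mRNAs take part in the cycle. In 58.1% of the 681 pairs 1 of the members started with U, and in 32.7% both did. Of all members 61.8% started with U, and the shares of pairs were not set against expected ones. The richest window of chromosome 17 alone held 617 of the 2722 pairs (ratio 3.17 within it). Without that window the ratio was 2.18.

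**Figure D4:**
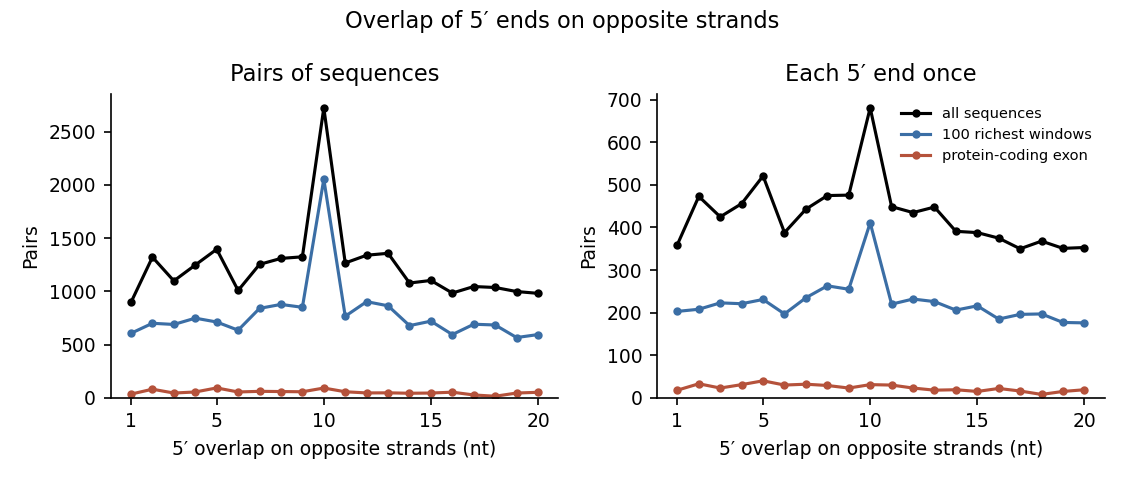
Number of opposite-strand pairs at each overlap of their 5′ ends from 1 to 20 nt, counted as pairs of sequences on the left and with each 5′ end once on the right, for all sequences (black), the 100 richest windows (blue) and protein-coding exons (red). A peak at 10 nt stands out for all sequences (2722 pairs, and 681 on the right) and for the windows. It does not for protein-coding exons, where only pairs with both members sense to such exons are counted.

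Antisense sequences numbered 200 or more on 32 genes. The noncoding gene CT025671.4 had 1786 antisense and 2 sense sequences. The pseudogene Gm18609 (1271 antisense and 0 sense) and Gm42811 (1257 and 6) lie on chromosome 6, and 5330409N07Rik on chromosome 12 had 850. The sequences matching these 4 genes lay inside windows among the 100 richest, and the ranges for Stox1 and Mfsd4a start in such windows. An antisense match gives the strand only and does not show that the gene is a target. Stox1, Cd247 and Mfsd4a were the protein-coding genes among the 10 genes with most. Stox1 had 846 antisense and 126 sense, Cd247, which encodes a T-cell receptor subunit, 783 and 0, and Mfsd4a 726 and 12. The antisense sequences of Cd247, between 167796789 and 167801259 of chromosome 1, lie inside the range of the sense sequences of Pou2f1, 167795324 to 167932770. Without the strand of the gene they match, these sequences would be read as coming from Cd247.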

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

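The tests of even coverage and of 5 drawn sequences in this part were chosen after the values it concerns had been seen. The results here are signals outside the size or the sources that the report describes.

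Sequences under 24 nt numbered 42069 (1.90% of the list), below the gel range that the protocol names. They made up 6.10% of sequences inside the 100 richest windows and 0.825% outside, and 63.2% of them started with U.

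The mitochondrial chromosome held 296 sequences, 183 of them in mitochondrial rRNA, with U first in 15.9% and a mean length of 26.7 nt.

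Annotated microRNA genes inside the 100 richest windows held 545 sequences in 18 genes, more per gene than the 758 sequences of 251 microRNA genes elsewhere. The windows were chosen for their number of sequences, so a higher number per gene inside would follow from that choice. Mir7222 on chromosome 2 had 85, Mir7217 on chromosome 17 had 76 and Mir7210 on chromosome 14 had 49. A long precursor that runs through the gene may be their source: 88.1% measured 24 to 32 nt, but so did 77.8% outside the windows, and since the gel set the sizes this test leaves the matter open. Cleavage with fixed ends, as for a microRNA, is not excluded by a median of 37.8% of a gene's sequences at its 2 most used 5′ ends in the 17 genes with 5 or more sequences, between the bounds set beforehand, although with 5 sequences drawn per gene that median averaged 58.6% inside and 100% in 50 such genes outside, so that 5′ ends were less fixed inside. The density in these genes was 2.52 times that of their window (median), between the bounds set for even coverage and for a separate source, so that the explanations cannot be told apart, and no biological explanation from the design was tested.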

How the results depend on the processing

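Of 54 alternative values 23 moved by less than their error or tolerance, 31 moved by more, and 0 changed direction. Many of these values are shares of a single list with no direction to change, so that the 0 says nothing about them. Settings that count each 5′ end once outside the overlap, that use 5′ ends with 5 or more 3′ ends or subsets of sequences for the overlap, or that take strand from any overlapping sequence, and all those for the structural RNA share, the 3′ untranslated share and the gene lists, were chosen after seeing the data. With each 5′ end counted once, first-base U was 60.8%, protein-coding exons 59.5%, no exon 33.4%, long noncoding RNA 3.60%, antisense 2.70%, the 100 richest windows 18.8%, the 3′ untranslated share 50.7%, and the 10-nt overlap 1.63 (z 5.11). Among 5′ ends with 5 or more 3′ ends, first-base U was 85.8% and A at position 10 was 34.7%. At 24 to 32 nt, protein-coding exons were 52.1%, no exon 40.7% and long noncoding RNA 3.73%. Leaving out structural RNA and microRNA genes gave 51.6% protein-coding exon and 41.3% no exon. Counting a sequence in every class gave 52.2% protein-coding exon, 3.96% long noncoding RNA and 3.53% antisense. Structural RNA was 0.180% with both strands of its genes and no split of shared sequences, with or without AY036118 and Gm42418. Without the split the sense strand alone gave 0.106%. Windows of 50 kb held 22.8%, and the 20 richest windows of 20 kb held 8.78%, fewer by construction. The overlap ratio was 1.80 (z 2.39) for pairs with both members sense to protein-coding exons and 2.71 (z 12.5) for pairs with neither. It was 2.21 with strand from any overlapping sequence, and 2.18 (z 7.67) without the window with most pairs. The cause was not tested in these cases. Percentiles of the 7 gene lists kept their side of the middle under both of their alternatives.

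Alternatives that need reads, libraries or repeats were not run: reads in place of distinct sequences, sequences with at least 2 reads, identity of the first 20 nt, TMM scaling, a minimum of 50 reads, and repeat-annotated reads only. The restriction to sequences with 1 genome position was not run either, since 1 position is listed for each sequence and the number of its genome positions is not given. No paired analysis was possible because each group has 1 library and the list carries no library column. Depth is unknown, so that a gene with 0 sequences was not detected at this depth rather than absent.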

Other observations

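The tests of X-linked genes, the minimum of 20 pairs for a window and the interval over genes for 3′ untranslated regions were chosen after the result was seen, and all patterns below were found on the same data that tested them.

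A window at 39980001 to 40000000 of chromosome 17, chosen after its values were seen, differed from the other rich windows. It held 1753 sequences, 99.8% of them in annotated exons, among them Gm42418 (1211 sense sequences), CT010467.1, annotated as rRNA (1527 antisense), and AY036118 (957 antisense). CT010467.1 and AY036118 are annotated on the minus strand and Gm42418 on the plus strand, so these sense and antisense matches run in the same direction. Adding those of AY036118 and Gm42418 to the sequences on either strand of structural RNA genes raised their number only from 3990 to 3995. The 3 genes thus do not stand for separate sequences. In this window U started 24% of the sequences of 24 to 32 nt. At an overlap of 10 nt it had 127 pairs, 1.07 times the mean of its other overlaps, against 1.44 to 5.16 times (median 3.42) in the 21 other rich windows with 20 or more pairs, while 15 windows with fewer pairs ranged from 0.679 to 7.74 times and 63 had 0 pairs.

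X-linked protein-coding genes carried few sequences, with a median of 0.818 per kb in 948 genes against 3.15 in 20807 autosomal genes, although the 0.853 of chromosome 14 was close to it. Shorter or fewer X-linked exons account for part of the gap at most, since length-matched random lists had a median of 1.67 per kb and the X-linked median was at percentile 0.01 of them. Multicopy X-linked genes lost from a list of single positions are argued against as the whole cause by the 581 X-linked genes with at least 1 sequence, whose median of 4.69 per kb was at percentile 0 of such lists (random median 7.58). Partial loss in genes with some unique sequence may still contribute. The level of the transcripts was not measured here, and no biological explanation was tested.

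U as the first base was less common inside the 100 richest windows, and the windows with more sequences had less of it (Spearman's rho -0.519 across 100 windows, which are not independent). Between sequences per kb and first-base U, rho was weaker, -0.134, across the 1328 protein-coding genes with 200 or more sequences. A lower U content of the transcripts in the windows is argued against, since the mean U share at positions 2 to 18 was 24.1% inside and 22.0% outside, a difference of -2.14 points (outside minus inside). Breakdown fragments of the cluster transcripts stay open: sequences without U fell outside 24 to 32 nt 0.804 times as often as those with U, which by the bound set beforehand would count against them, but the gel set the sizes, a limit weighed after the value was seen, so that this excludes nothing. Another candidate explanation that the data leave open is that rare 5′ ends are each listed once where sampling is deep: inside the windows U started 40.5% of 5′ ends with 1 listed 3′ end and 79.0% of those with 5 or more, 38.5 points apart. The same contrast outside was 55.6% against 90.5%, so that at an equal number of 3′ ends the windows remained lower, and read numbers would be needed to settle it.

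A at position 10 rose with length, from 26.6% at 25 nt to 36.8% at 29 nt. The hypothesis that this reflects partners of the amplification cycle is left undecided. Sequences of 29 nt had a partner at 10 nt 0.634 times as often as those of 25 nt (0.140% against 0.221%), which by the bound set beforehand counts against it. However, 2053 of the 2722 pairs lay in the 100 richest windows, where 11.1% of sequences measured 29 to 32 nt against 22.1% outside. No other overlap was compared by length, so length and location cannot be told apart here. The mean A share at the positions 4 to 9 and 11 to 16 rose by 4.80 points against 10.1 at position 10, and position 22 rose by 12.9, so a general A content of longer sequences remains open.

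The hypothesis that long 3′ untranslated regions account for the share of sequences found there is left undecided by the bounds of 3 and 10 points set beforehand, as the share was 5.83 points above that expected from length. The excess had a 95% interval of 5.35 to 6.39 points from 1000 draws of the 15433 genes, so that length may account for most of the share but not for this excess. The expected share took only length into account. U started 75% of sequences in 3′ untranslated regions, 59.4% in coding sequence and 62.3% in 5′ untranslated regions. The excess was not computed by first base, so it does not show a preference for the region apart from that for U. The hypothesis that precursors are cut into adjoining pieces found no support in these distinct sequences, as 3′ ends were followed directly by a 5′ end 1.01 times as often as at gaps of 5 to 20 nt. The test reads the listed 3′ ends without read numbers. It cannot decide the matter if 3′ ends are shortened after the cut.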
